A study of Mus musculus with 6 samples.

How the data were processed

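RNA-seq was analysed from 6 libraries of primary mouse bone marrow stromal cells, the non-blood cells of the marrow that give rise to bone-forming osteoblasts and to fat cells. Of these, 3 were wild type (WT) and 3 carried the Pth1rΔNLS allele of the parathyroid hormone receptor, named for the loss of its nuclear localisation signal. The series design text describes the Pth1rΔNLS animals as heterozygous. Per the labels' protocols, cells were flash frozen, RNA was extracted with TRIzol, and libraries were built from total RNA with an Illumina TruSeq RNA kit. How the cells were isolated, whether they were cultured or sorted, and whether each library came from a separate mouse are not given in the sources used here. The p-values therefore measure only the spread between these samples, which may be partly technical.

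Per the submitters' processing notes, reads were handled with HISAT2, StringTie and the mouse build mm10. Versions, settings and the annotation are not given in the sources used here. The deposited table holds 1 value per transcript and library for 23351 transcripts, and the authors' header names no unit. The deposited values were taken as FPKM, fragments scaled by transcript length and by the mapped fragments of each library, because their sums behaved as FPKM do. The sum of value times transcript length came to 74.99 to 78.1% of the total that FPKM over all mapped fragments would give, with a coefficient of variation of 1.49% between libraries. The plain sums varied more, by 3.46%, from 315872 to 343328 per library. The lowest mean of any listed transcript was 0.251 FPKM, and 11870 of the 11896 named genes were protein-coding, so other transcripts were not analysed here. Sequencing depth is unknown. Whole-read steps were searched for in the low values, and the best step left 27.5 to 29.5% of them within 0.1 of a whole number against 20.0% by chance, so read numbers could not be recovered and no interval from counting is given. FPKM share 1 total, so a gain by abundant transcripts lowers all others. StringTie also divides reads between transcripts of a gene, so an exact 0 can be a failed estimate. Whether strand was used is not given in the sources used here, so overlapping genes on opposite strands, and near-identical copies such as Bglap and Bglap2, Arxes1 and Arxes2, Hspa1a and Hspa1b, and the histone genes, are uncertain.

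Transcripts were matched by identifier, ignoring the version suffix, to the GENCODE M21 annotation of mm10, which gave names to 23300 of them (22174, or 94.96%, with the same version). The 51 without a name held at most 0.117% of the FPKM of any library and were left out. Coordinates are 1-based on mm10. FPKM of a gene's listed transcripts were summed, and 6066 genes had 1 listed transcript. Another 7 symbols belonged to several gene identifiers, which were kept apart.

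Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend) on log2(FPKM + 1), for the 10905 genes with a mean of at least 1 FPKM over the 6 libraries. The contrast was Pth1rΔNLS minus WT, p-values were two-sided and adjusted by Benjamini-Hochberg, and the threshold was an adjusted p of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, except where cell types are weighed relative to a list's mean. Those are on log2(FPKM), for genes with an exact 0 in no library, since a shift in cell shares changes FPKM by a shared factor. Errors beside FPKM are standard deviations over 3 libraries, and SE is the moderated limma standard error. The planned test for FPKM was used as written. Gene lists were tested with limma camera at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the 27 lists with at least 5 tested members out of 36 lists fixed in advance; 181 list members were not analysed here because the table does not list them. A first run of camera without a variance trend passed the same 14 lists. For each list, members past the threshold were counted both over all genes and adjusted over the list alone. No member of a list of sex-linked genes, intended as a sample check, was analysed here. Table handling used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots used matplotlib 3.10.9.

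The genes to be named, the lists, the test and most alternatives were fixed before the data were examined. Named genes are 17 chosen for the question, namely Pth1r, Thra, Thrb, Dio2, Klf9, Runx2, Sp7, Alpl, Col1a1, Bglap, Sost, Tnfsf11, Tnfrsf11b, Pparg, Adipoq, Lepr and Cxcl12. To these were added the 10 higher and 10 lower genes of largest fold change among those past the threshold whose libraries did not overlap between genotypes, leaving out predicted or unnamed models. Up to 4 members of smallest p came from each list past its test and from each list of another cell type (of highest mean where fewer than 4 were tested), with any gene that a rule on outlying samples or a left-out library singled out. Genes outside this rule are said to be chosen after their values were seen. Some genes that belong to the lists are not reported here by name.

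The statistics were tested on simulated data drawn from these libraries' means and spreads over 10905 genes. Of 100 genes changed 2-fold, 65% were recovered, and of 100 changed 1.5-fold, 37%, with 2 unchanged genes called and 0 wrong signs. The list that was shifted was called, and 0 others were. The simulation took means and spreads from the libraries, but not the correlation between genes. In the real lists the estimated correlation ran from -0.0735 (osteoclast support factors) to 0.2352 (antigen presentation). The simulation therefore cannot show how often camera at the preset correlation calls unshifted lists whose members are correlated. Alternatives covered the replicate number as a block, each library left out in turn, other pseudocounts, filters, scalings and limma options, transcripts tested singly, and other list tests. Further ones, chosen after seeing the data, rescaled nuclear genes without mitochondrially encoded transcripts, kept only genes with an exact 0 in no library or with 1 listed transcript, or left out the 2 libraries of highest and lowest mitochondrial share. The values relative to a list's mean were also computed on log2(FPKM + 1).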

Results

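The data comprised 6 RNA-seq libraries of primary mouse bone marrow stromal cells, 3 WT and 3 Pth1rΔNLS, with 11810 to 11834 genes above 0 FPKM in each. Depth in reads is unknown. Pairs of libraries shared at most 1 identical transcript value above 0, and a principal component with 46.9% of the variance placed the WT libraries at -24.4, -20.3 and -22.1 and the Pth1rΔNLS libraries at 23.3, 21.3 and 22.1. Mitochondrially encoded transcripts made up 6.47, 12.8 and 9.33% of FPKM in WT libraries 1, 2 and 3 and 18.2, 12.8 and 10.6% in Pth1rΔNLS libraries 1, 2 and 3. The comparison asked how gene expression in marrow stromal cells differed when the receptor carried the ΔNLS allele, in a study concerned with the nuclear receptor, thyroid hormone signalling and bone mass.

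Pth1r, which encodes the receptor for parathyroid hormone and its related protein (ENSMUSG00000032492.14, chromosome 9, 110722085 to 110747145, mm10), was lower in Pth1rΔNLS cells. Its level was 7.98, 4.72 and 6.24 FPKM in the WT libraries and 1.91, 1.72 and 2.99 FPKM in the Pth1rΔNLS libraries, with means of 6.31 ± 1.63 and 2.21 ± 0.683 (SD, n = 3 each). The log2 fold change was -1.19 (SE 0.22, limma adjusted p = 0.0140), and the exact two-sided permutation test gave p = 0.1, the smallest possible with 20 assignments. Both listed transcripts, 2 of 6 annotated, had lower means, 5.03 against 1.72 FPKM for ENSMUST00000006005.11 and 1.28 against 0.484 FPKM for ENSMUST00000196057.1. The sum over transcripts does not measure the part of the gene that the allele removes, so it does not check the genotype labels. In the same libraries the osteoblast list fell (median -0.85) and 14 of 20 macrophage genes rose. A change in cell shares and a change of Pth1r within cells were therefore not told apart. The call was lost without WT 3 (adjusted p = 0.0510), Pth1rΔNLS 1 (0.0524) or Pth1rΔNLS 2 (0.0528), and without both libraries of extreme mitochondrial share (WT 1 and Pth1rΔNLS 1; fold change -0.97, adjusted p = 0.108).

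Pth1rΔNLS libraries had lower transcript levels of osteoblast, WNT and contractile genes and higher levels of cell cycle and macrophage genes. Here and in the paragraphs below, a change in cell shares and a change within cells were not told apart. Of 10905 genes tested, 1886 changed (limma, Benjamini-Hochberg adjusted p under 0.05), 757 higher and 1129 lower in Pth1rΔNLS. Among them, 35 were at least 2-fold higher and 285 at least 2-fold lower. All 1886 had non-overlapping libraries, as had 36.6% of tested genes against 10% by chance. The count fell to 1209 without WT 1, 1103 without WT 3, 1146 without Pth1rΔNLS 1, 1051 without Pth1rΔNLS 2 and 1115 without Pth1rΔNLS 3. It was 620 (191 higher, 429 lower) without the 2 libraries of extreme mitochondrial share. Any call lost in that setting may reflect the smaller number of samples rather than mitochondrial content. Of 27 gene lists tested, 14 passed camera at the preset correlation. With an estimated correlation 8 did: cell cycle, macrophage, osteoblast, marrow stromal, smooth muscle, WNT, BMP and TGF-beta, and matrix metalloproteinases.

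**Figure D1:**
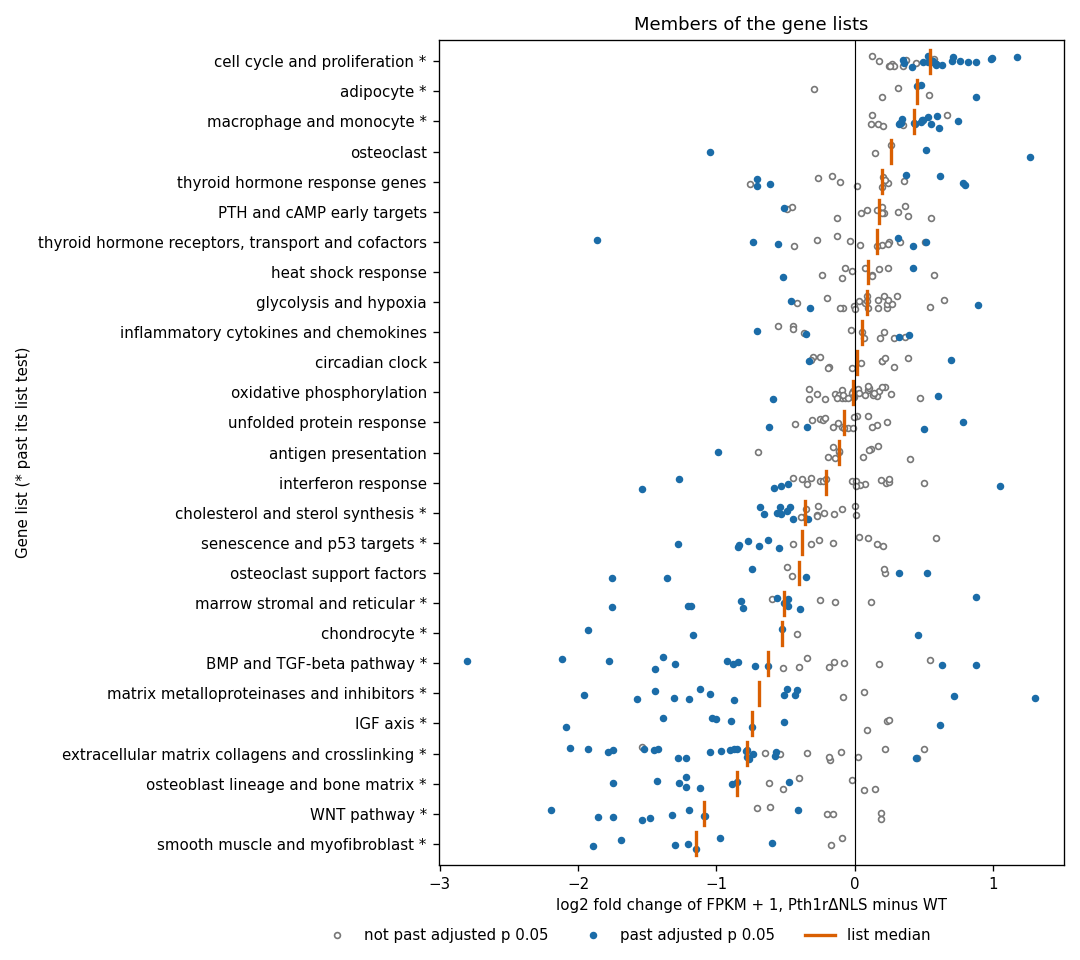
Log2 fold change of FPKM + 1 (x axis, Pth1rΔNLS minus WT) for each tested member of the 27 gene lists (y axis, ordered by median), with filled points past an adjusted p of 0.05, open points not past it, orange bars for list medians and asterisks for lists past camera at the preset correlation. Cell cycle members have a median of 0.55, macrophage members 0.43 and smooth muscle members -1.15.

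Genes of the osteoblast lineage and bone matrix fell in Pth1rΔNLS cells. Alpl, the alkaline phosphatase needed for mineralisation (chromosome 4, 137741733 to 137796384), fell from 18.8 ± 0.244 to 6.33 ± 0.253 FPKM (log2 fold change -1.43, SE 0.07, adjusted p = 0.000180). Sp7, which encodes the osteoblast transcription factor osterix (chromosome 15, 102356606 to 102367182), fell from 4.28 ± 0.0586 to 1.19 ± 0.144 FPKM (-1.27, adjusted p = 0.000787). Col1a1, encoding the main collagen chain of bone (chromosome 11, 94936224 to 94953042), fell from 668 ± 145 to 196 ± 23.7 FPKM (-1.75, adjusted p = 0.00156). The matrix genes Sparc (1608 ± 51.6 to 867 ± 8.14 FPKM) and Ibsp, encoding bone sialoprotein (11.3 ± 0.763 to 4.30 ± 0.249 FPKM), also fell, with adjusted p of 0.000603 and 0.000638. Of 15 tested members, 0 rose, 9 fell and 6 did not pass, and 12 fell adjusted over the list alone. The list median was -0.85 (camera adjusted p = 1.86e-06, or 0.0419 with an estimated correlation). Bglap, encoding osteocalcin, was below the expression filter, at 1.24 ± 0.11 FPKM in WT and 0.0819 ± 0.142 FPKM in Pth1rΔNLS. Runx2, the transcription factor that starts osteoblast differentiation, fell from 6.91 ± 0.353 to 4.69 ± 0.493 FPKM (-0.48, adjusted p = 0.0250), with 1 of 13 annotated transcripts listed. Its call was lost when any library but Pth1rΔNLS 2 was left out (adjusted p 0.0590 to 0.0821) and without both libraries of extreme mitochondrial share (0.160). In the same libraries the macrophage list rose, with 14 of 20 members higher (median 0.43). Among 3 tested osteocyte genes, 1 rose, Pdpn, which encodes podoplanin (5.50 ± 0.276 to 10.7 ± 0.664 FPKM, adjusted p = 0.00190; chosen after its values were seen), also adjusted over the list alone. Sost was not analysed here.

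Of 33 genes for collagens, collagen-modifying enzymes and other matrix proteins 21 fell in Pth1rΔNLS (camera adjusted p = 0.0966 with an estimated correlation), beside the higher macrophage list (14 of 20 members). Col12a1, a fibril-associated collagen, fell from 156 ± 7.02 to 44.7 ± 2.41 FPKM, and Postn, encoding the matrix protein periostin, from 106 ± 9.62 to 24.5 ± 1.51 FPKM (adjusted p = 9.03e-05 and 0.000109). Col8a1 fell from 278 ± 11 to 103 ± 3.12 FPKM and Col11a1, a fibrillar collagen, from 35.0 ± 4.16 to 8.43 ± 0.848 FPKM. Of 33 tested members, 1 rose, 21 fell and 11 did not pass, against 2 and 24 adjusted over the list alone (median -0.78, camera adjusted p = 3.22e-11; adjusted p = 0.0966 with an estimated correlation). The member that rose was Plod1, a collagen lysyl hydroxylase (log2 fold change 0.44, adjusted p = 0.0346; chosen after its values were seen), and no member passed as higher without any 1 of WT 1, WT 3 or Pth1rΔNLS 1, 2 and 3. Of 16 metalloproteinase and inhibitor genes, 2 rose and 12 fell, also adjusted over the list alone (median -0.69, camera adjusted p = 2.27e-06, or 0.0419 with an estimated correlation). Adamts5, an aggrecan-cleaving protease, fell from 15.6 ± 1.58 to 3.26 ± 0.0926 FPKM and Adamts12 from 24.3 ± 2.60 to 7.47 ± 0.163 FPKM. Mmp2, a gelatinase, fell from 98.0 ± 7.78 to 47.0 ± 4.20 FPKM and Mmp11 from 8.95 ± 1.04 to 2.66 ± 0.437 FPKM. Those that rose were Mmp12, known as macrophage elastase (1.31, adjusted p = 0.0108), and Mmp10 (0.72, adjusted p = 0.0202), both chosen after their values were seen, and 1 of the list passed as higher when any library but WT 3, or both libraries of extreme mitochondrial share, were left out.

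Of 5 tested chondrocyte genes, 1 rose and 3 fell, against 1 and 4 adjusted over the list alone (median -0.53, camera adjusted p = 0.0449; adjusted p = 0.247 with an estimated correlation). Col11a1, also among the matrix genes, had the largest fall (log2 fold change -1.93, adjusted p = 0.000264), and Col10a1, the collagen of hypertrophic chondrocytes, fell from 6.76 ± 0.135 to 4.38 ± 0.25 FPKM. Col2a1, the main cartilage collagen, fell from 53.7 ± 16.0 to 22.9 ± 4.13 FPKM (adjusted p = 0.0219), while Sox9, the transcription factor of cartilage formation, rose from 6.45 ± 0.212 to 9.24 ± 0.971 FPKM (adjusted p = 0.0271). The list's call was lost without WT 3 (adjusted p = 0.0641), Pth1rΔNLS 2 (0.0536) or Pth1rΔNLS 3 (0.0579), without a filter on low values (0.0534), with ranks (0.10), and without both libraries of extreme mitochondrial share (0.0501), where 0 members rose and 1 fell. Col2a1 lost its call when any library but WT 2 was left out (0.0541 to 0.0729), and Sox9 without WT 1, WT 3 or Pth1rΔNLS 2 or 3 (0.0808 to 0.0950). The macrophage list, with 14 of 20 members higher, moved in these libraries too.

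Of 16 tested WNT pathway genes 10 fell in Pth1rΔNLS cells, and of 21 BMP and TGF-beta genes 11 fell, beside the higher macrophage list (14 of 20 members, median 0.43). In the WNT list, the secreted antagonist Sfrp1 fell from 93.7 ± 3.70 to 40.2 ± 0.440 FPKM and the agonist Rspo2, encoding R-spondin, from 46.4 ± 3.17 to 16.0 ± 0.851 FPKM. Dkk3, from the Dickkopf family, fell from 98.9 ± 3.22 to 46.2 ± 0.676 FPKM, and Ccn4, a matricellular gene induced by WNT, from 42.1 ± 2.55 to 13.9 ± 1.03 FPKM. In the WNT list 0 rose and 10 fell, against 0 and 12 adjusted over the list alone (median -1.09, camera adjusted p = 3.81e-08, or 0.0419 with an estimated correlation). Bmp4, a bone morphogenetic protein (chromosome 14, 46383520 to 46390669), fell from 42.1 ± 3.09 to 5.17 ± 0.457 FPKM (log2 fold change -2.80, SE 0.10, adjusted p = 9.03e-05). Fst, encoding the activin inhibitor follistatin, fell from 58.8 ± 1.91 to 12.8 ± 0.893 FPKM, Tgfb3 from 57.7 ± 3.95 to 16.1 ± 0.763 FPKM and Ccn2, encoding connective tissue growth factor, from 788 ± 26.5 to 439 ± 8.53 FPKM. In the BMP and TGF-beta list 2 rose, 11 fell and 8 did not pass, against 2 and 14 adjusted over the list alone (median -0.63, camera adjusted p = 8.61e-06, or 0.0419 with an estimated correlation). The members that rose were the BMP antagonist Grem1 and Tgfb1 (51.1 ± 5.57 to 79.7 ± 8.53 FPKM, adjusted p = 0.0135; chosen after its values were seen), and 1 passed as higher without Pth1rΔNLS 3.

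In the IGF list, Pappa, a protease that cleaves IGF-binding proteins, fell from 33.4 ± 3.94 to 7.07 ± 0.489 FPKM (log2 fold change -2.09, adjusted p = 0.000168). The binding proteins Igfbp5 (136 ± 9.84 to 51.3 ± 0.900 FPKM) and Igfbp4 (364 ± 35.3 to 180.1 ± 4.32 FPKM) fell, as did Irs1, an insulin receptor substrate (13 ± 0.280 to 7.37 ± 0.403 FPKM). Igf1 itself, outside the naming rule and chosen after its values were seen, rose from 126 ± 12.9 to 193 ± 16.5 FPKM (adjusted p = 0.00941). Of 11 tested members 1 rose and 7 fell, against 3 and 7 adjusted over the list alone (median -0.75, camera adjusted p = 0.00586; adjusted p = 0.0925 with an estimated correlation). Ranks in place of moderated statistics also ended the list's call (0.0890), and 2 members rose without WT 2 and 0 without both libraries of extreme mitochondrial share. The macrophage list stood higher in 14 of 20 members.

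Marrow stromal and contractile genes were lower in Pth1rΔNLS, again with 14 of 20 macrophage genes higher. Cxcl12, the chemokine that retains blood progenitors in the marrow (chromosome 6, 117168535 to 117181367), fell from 283 ± 25.9 to 82.6 ± 3.17 FPKM (log2 fold change -1.76, SE 0.08, adjusted p = 0.000143). The transcription factors Foxc1 (11.4 ± 0.194 to 4.38 ± 0.327 FPKM) and Ebf3 (9.61 ± 0.532 to 3.67 ± 0.25 FPKM) of marrow reticular cells fell, while Grem1 rose from 32.9 ± 3.27 to 61.2 ± 2.19 FPKM (0.88, adjusted p = 0.00155). Of 15 tested marrow stromal genes 1 rose and 10 fell, also adjusted over the list alone (median -0.51, camera adjusted p = 1.90e-05, or 0.0419 with an estimated correlation). The number lower was 6 without Pth1rΔNLS 1, 5 without Pth1rΔNLS 2 and 4 without both libraries of extreme mitochondrial share, and Lepr was not analysed here. Of 9 smooth muscle and myofibroblast genes 0 rose and 7 fell, also adjusted over the list alone (median -1.15, camera adjusted p = 8.96e-07, or 0.0419 with an estimated correlation). Acta2, encoding smooth muscle actin, fell from 1518 ± 75 to 658 ± 36.1 FPKM, Mylk, a myosin light chain kinase, from 65.9 ± 3.07 to 19.7 ± 0.325 FPKM and Lmod1, encoding leiomodin, from 23.6 ± 1.31 to 5.64 ± 0.371 FPKM. Actg2, another smooth muscle actin, fell from 253 ± 14.4 to 129 ± 18.2 FPKM.

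Proliferation genes rose in Pth1rΔNLS cells. Cenpe, a kinetochore motor, rose from 5.81 ± 0.403 to 12.5 ± 0.717 FPKM (log2 fold change 0.98, SE 0.09, adjusted p = 0.00122), and Mki67, encoding the proliferation antigen Ki-67, from 12.5 ± 1.64 to 25.6 ± 1.54 FPKM (0.99, adjusted p = 0.00211). Top2a, a DNA topoisomerase, rose from 19.9 ± 0.859 to 33.1 ± 1.04 FPKM and Mcm5, a subunit of the replicative helicase, from 7.22 ± 0.313 to 12.4 ± 0.317 FPKM. Of 30 tested members 20 rose, 0 fell and 10 did not pass, against 27 and 0 adjusted over the list alone (median 0.55, camera adjusted p = 2.12e-14, or 0.0213 with an estimated correlation). Macrophage genes rose in the same libraries (14 of 20). The number higher was 13 without Pth1rΔNLS 2, 13 without Pth1rΔNLS 3 and 8 without both libraries of extreme mitochondrial share. Of 16 senescence and p53 target genes 0 rose and 7 fell, against 1 and 8 adjusted over the list alone (median -0.38, camera adjusted p = 0.00657; adjusted p = 0.268 with an estimated correlation). Cdkn2a, the locus of the cell cycle inhibitor p16 and of Arf, fell from 48.2 ± 3.56 to 26.4 ± 2.69 FPKM, and the p53 targets Trp53inp1 from 28.0 ± 1.58 to 15.3 ± 0.875 FPKM and Ccng1 from 180.2 ± 11.5 to 123 ± 0.437 FPKM.

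Macrophage and monocyte genes, included as markers of another cell type that marrow preparations hold, were abundant in both genotypes and rose in Pth1rΔNLS. Lyz2, encoding lysozyme, stood at 2231 ± 75.5 FPKM in WT and 2811 ± 32.2 FPKM in Pth1rΔNLS (log2 fold change 0.33, adjusted p = 0.0285; chosen after its values were seen). Laptm5, a lysosomal membrane protein of blood cells, rose from 150.4 ± 2.56 to 253 ± 12.2 FPKM (0.74, adjusted p = 0.000866) and Tyrobp, a myeloid signalling adaptor, from 286 ± 6.23 to 439 ± 16.1 FPKM. Csf1r, the receptor for macrophage colony-stimulating factor, rose from 158 ± 8.96 to 222 ± 10.7 FPKM and the complement gene C1qa from 423 ± 20 to 613 ± 51.5 FPKM. Of 20 members 14 rose, 0 fell and 6 did not pass, against 16 and 0 adjusted over the list alone (median 0.43, camera adjusted p = 2.74e-09, or 0.0419 with an estimated correlation). The number higher was 7 without WT 1, 6 without WT 3, 9 without Pth1rΔNLS 1, 6 without Pth1rΔNLS 2, 8 without Pth1rΔNLS 3 and 4 without both libraries of extreme mitochondrial share, when C1qa also lost its call (adjusted p = 0.0557).

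The osteoclast list did not pass camera (5 tested, 2 higher and 1 lower, 3 and 1 adjusted over the list alone, median 0.26, adjusted p = 0.165). Atp6v0d2, a proton pump subunit of osteoclasts and macrophages, rose from 10.2 ± 2.15 to 25.9 ± 3.87 FPKM and Itgb3, an integrin chain, from 12.4 ± 0.912 to 18.2 ± 1.75 FPKM, while Ctsk, encoding cathepsin K, fell from 66.5 ± 5.39 to 31.6 ± 1.76 FPKM. Tnfrsf11a, encoding the receptor RANK, was at 15.5 ± 1.10 and 18.7 ± 0.866 FPKM (adjusted p = 0.0843, or 0.0418 with array weights). Itgb3 lost its call without WT 3 or Pth1rΔNLS 2 or 3 (0.0547 to 0.0590) and without both libraries of extreme mitochondrial share (0.0626), and 1 list member then passed as higher in each case. Among 2 tested neutrophil genes Mmp8, a collagenase, rose (0.655 ± 0.358 to 2.67 ± 0.347 FPKM) and Mcpt8, known as a basophil protease, fell (80.0 ± 10.6 to 39.7 ± 3.82 FPKM), whereas S100a8 (0.408 ± 0.3 and 0.631 ± 0.312 FPKM) and Camp (0.599 ± 0.306 and 0.166 ± 0.287 FPKM) were below the filter. Both tested B cell genes rose, Blnk, an adaptor also made by macrophages, from 25.8 ± 0.842 to 41.4 ± 2.72 FPKM and Cd22 from 0.890 ± 0.146 to 1.75 ± 0.213 FPKM. Both tested genes of the platelet list rose as well, the chemokines Pf4 (361 ± 54.8 to 511 ± 46.1 FPKM, adjusted p = 0.0401) and Ppbp (0.696 ± 0.233 to 2.24 ± 0.336 FPKM, adjusted p = 0.00923), while Treml1 was below the filter (0.381 ± 0.659 and 1.02 ± 1.08 FPKM). Of this list's 10 members 3 were listed, and Ppbp and Treml1 were near the floor. The Pf4 level alone therefore does not show platelets, and its cell source was not tested. Of 4 endothelial genes 2 fell, the adhesion molecule Cdh5 (4.05 ± 0.146 to 2.30 ± 0.165 FPKM) and Emcn, encoding endomucin (4.28 ± 1.18 to 2.26 ± 0.231 FPKM). Pecam1 (2.09 ± 0.297 and 1.43 ± 0.324 FPKM) and Vwf (1.65 ± 0.396 and 2.19 ± 0.670 FPKM) did not pass. The counts of these 4 small lists were the same adjusted over the list alone. Cd4, the only T cell gene tested (2.47 ± 0.343 and 2.69 ± 0.524 FPKM), and the muscle genes Acta1 (1.51 ± 0.463 and 1.11 ± 0.262 FPKM) and Tnni2 (1.70 ± 1.5 and 0.632 ± 1.09 FPKM) did not pass over all genes or adjusted over the list alone. Erythroid and mast cell genes were not analysed here. Calls in these small lists were often lost when 1 library was left out. Cd22 lost its call without any 1 of the 6 libraries (adjusted p 0.0554 to 0.0995), Emcn without any but WT 2 (0.0690 to 0.124) and Pf4 without any but WT 1 (0.0657 to 0.125) or without the limma trend (0.0516). Leaving out both libraries of extreme mitochondrial share ended the calls of Cd22 (0.145), Emcn (0.162), Cdh5 (0.0890), Mmp8 (0.0892) and Ppbp (0.0730), with fewer samples. The log2 fold changes were then 0.58 for Cd22 (0.54 with all 6 libraries) and -0.62 for Cdh5 (-0.62). They were smaller for Emcn (-0.47, against -0.68), Mmp8 (1.05, against 1.17) and Ppbp (0.85, against 0.94).

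Thyroid hormone signalling genes went both ways. Thra, which encodes a nuclear thyroid hormone receptor (chromosome 11, 98740638 to 98769006), fell from 10.6 ± 1.79 to 6.83 ± 0.558 FPKM (log2 fold change -0.56, SE 0.14, adjusted p = 0.0387). Thrb, the other receptor gene, was at 2.85 ± 0.221 and 2.20 ± 0.443 FPKM (-0.27, adjusted p = 0.241), and Klf9, a direct target of the receptors, at 8.54 ± 0.934 and 6.93 ± 0.385 FPKM (-0.26, adjusted p = 0.148). Dio3, the deiodinase that inactivates thyroid hormone, fell from 17.3 ± 1.90 to 4.01 ± 0.261 FPKM (-1.86, adjusted p = 0.000252). Members that rose were the corepressor Ncor1 (0.31), the transporter Slc16a10 (0.42) and Itgb3 (0.52), and of these genes Dio3, Ncor1 and Slc16a10 were chosen after their values were seen. Of 17 tested receptor, transport and cofactor genes 3 rose and 3 fell, against 4 and 4 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.561). Its median of 0.16 and camera's direction were upward and its mean of -0.06 was not. The median was 0.06 without WT 1, 0.05 without WT 2 and 0.05 without both libraries of extreme mitochondrial share. Of 17 response genes 4 rose and 3 fell, against 4 and 4 adjusted over the list alone (median 0.20, or 0.0045 without WT 2 and 0.12 without Pth1rΔNLS 3; adjusted p = 0.408). Those higher were Ucp2 (0.80), Cpt1a (0.78), Igf1 (0.62) and Mbp (0.37) and those lower Me1 (-0.71), Fgfr1 (-0.71) and Hif1a (-0.61), all chosen after their values were seen. Dio2 was not analysed here. In these libraries 14 of 20 macrophage genes rose and the osteoblast list fell (median -0.85). Changes of these thyroid hormone genes within cells were therefore not told apart from a change in cell shares. Thra lost its call when any library but WT 2 was left out (adjusted p 0.0822 to 0.113) and without both libraries of extreme mitochondrial share (0.226). Of the receptor list, 1 rose and 1 fell without WT 3 or Pth1rΔNLS 1, and 0 rose and 1 fell without Pth1rΔNLS 2, Pth1rΔNLS 3 or both libraries of extreme mitochondrial share. Of the response genes 2 rose without both.

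Early targets of parathyroid hormone and cyclic AMP did not move as a list (14 tested, median 0.18, or 0.09 without Pth1rΔNLS 2, camera adjusted p = 0.408). Of its members 0 rose and 1 fell, also adjusted over the list alone, namely Mmp13, a collagenase (260 ± 18.3 to 182 ± 9.31 FPKM, adjusted p = 0.00730; chosen after its values were seen). Without WT 2, 1 rose and 2 fell. Tnfsf11, encoding the osteoclast-forming factor RANKL, was at 1.99 ± 0.311 and 1.14 ± 0.373 FPKM (-0.49, adjusted p = 0.0994). Tnfrsf11b, encoding its decoy receptor osteoprotegerin (chromosome 15, 54250619 to 54278484), fell from 48.1 ± 6.94 to 18.1 ± 1.22 FPKM (-1.36, adjusted p = 0.000866). Of 10 osteoclast support factors 2 rose and 4 fell, against 2 and 6 adjusted over the list alone (median -0.40, camera adjusted p = 0.165). Those that fell were Csf1 (231 ± 14.4 to 181 ± 9.91 FPKM), Lgr4 (-0.74), Tnfrsf11b and Cxcl12, and those that rose Sema3a (0.52) and Ccl2 (0.32), with Csf1, Lgr4, Sema3a and Ccl2 chosen after their values were seen, beside 14 of 20 macrophage genes higher. No member passed as higher without any 1 of WT 1, WT 3 or Pth1rΔNLS 1, 2 and 3, and 2 fell without both libraries of extreme mitochondrial share.

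In the adipocyte list, the fatty acid carriers Fabp4 (31.9 ± 0.612 to 45.1 ± 3.38 FPKM) and Cd36 (179 ± 33.5 to 327 ± 27.9 FPKM) and the lipase Lpl (112 ± 8.94 to 154 ± 6.15 FPKM) rose. Macrophages also express these 3 genes, and 14 of 20 macrophage genes rose. Pparg, the regulator of fat cell formation, was at 11.3 ± 1.75 and 8.96 ± 0.622 FPKM (adjusted p = 0.162), Cebpa at 24.5 ± 5.28 and 35.9 ± 6.19 FPKM (adjusted p = 0.115), and Adipoq, encoding adiponectin, was below the filter (0.684 ± 0.274 and 0.815 ± 0.388 FPKM). Of 7 tested members 3 rose and 0 fell, also adjusted over the list alone (median 0.45, camera adjusted p = 0.00930; adjusted p = 0.0966 with an estimated correlation). The list's call was lost without a filter on low values (0.166), and without both libraries of extreme mitochondrial share 0 members passed. Of 20 sterol synthesis genes 0 rose and 9 fell, also adjusted over the list alone (median -0.36, camera adjusted p = 3.35e-05; adjusted p = 0.0925 with an estimated correlation). Among these enzymes were Cyp51 (20.8 ± 1.67 to 12.5 ± 0.468 FPKM), Hsd17b7 (11.7 ± 1.05 to 7.04 ± 0.365 FPKM), Idi1 (16.3 ± 0.457 to 10.7 ± 0.841 FPKM) and Hmgcs1 (29.0 ± 1.27 to 19.8 ± 1.93 FPKM). The number lower was 5 without WT 1, WT 3, Pth1rΔNLS 2 or Pth1rΔNLS 3, and 1 without both libraries of extreme mitochondrial share, when Hsd17b7 (0.0754), Idi1 (0.0854) and Hmgcs1 (0.10) were not past the threshold.

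Among the genes of largest fall were Ptx3, a secreted pattern recognition protein (chromosome 3, 66219910 to 66225805), from 87.8 ± 6.88 to 9.31 ± 0.388 FPKM (log2 fold change -3.10, SE 0.08, adjusted p = 7.50e-05), and Palmd, from 22.2 ± 1.75 to 1.78 ± 0.304 FPKM (-3.06). Next came Bmp4, the imprinted gene Mest (5.71, 8.33 and 7.46 FPKM in WT and 0, 0 and 0.863 FPKM in Pth1rΔNLS, with 1 of 11 annotated transcripts listed), the cysteine dioxygenase Cdo1 (21.9 ± 1.82 to 2.60 ± 0.265 FPKM) and Arxes2 (30.6 ± 1.14 to 4.25 ± 0.542 FPKM). Npr3, the clearance receptor for natriuretic peptides, fell from 18.4 ± 1.67 to 2.58 ± 0.171 FPKM, Rflnb from 59.6 ± 6.31 to 10.6 ± 0.540 FPKM and Col8a2 from 13.2 ± 2.44 to 1.96 ± 0.298 FPKM. Casp12 was at 7.91, 4.55 and 7.44 FPKM in WT and 0.0624, 2.33 and 0 FPKM in Pth1rΔNLS, with 2 of 5 transcripts listed. It lost its call without WT 1, WT 3 or Pth1rΔNLS 1 or 3 (adjusted p 0.0706 to 0.0738), with a pseudocount of 0.1 (0.0529) and without both libraries of extreme mitochondrial share (0.158).

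**Figure D2:**
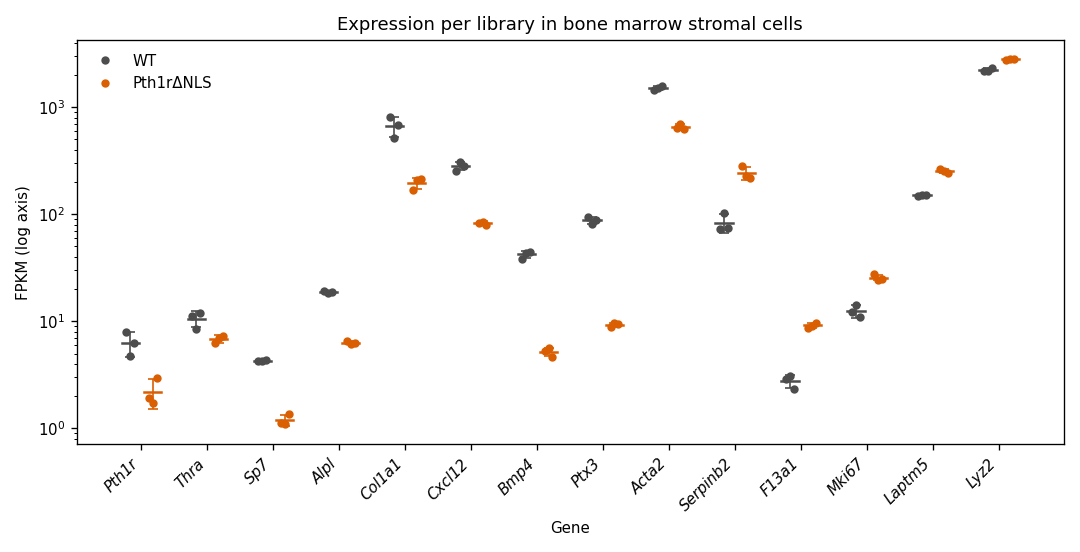
FPKM in each library (points), with group mean and SD (bars), on a log y axis for named genes in WT and Pth1rΔNLS (n = 3 each). Ptx3 has means of 87.8 in WT and 9.31 in Pth1rΔNLS, and Mki67 has means of 12.5 and 25.6.

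Among the genes of largest rise, Serpinb2, encoding plasminogen activator inhibitor 2 (chromosome 1, 107511423 to 107535478), rose from 83.7 ± 17.4 to 241 ± 33.5 FPKM (log2 fold change 1.53, SE 0.16, adjusted p = 0.00195). F13a1, a coagulation factor chain also made by macrophages, rose from 2.76 ± 0.388 to 9.15 ± 0.509 FPKM, and Myo5a, a vesicle-carrying myosin, from 25.3 ± 2.81 to 66.1 ± 9.33 FPKM. Foxm1, a transcription factor of cell division, rose from 0.677 ± 0.114 to 3.98 ± 1.41 FPKM and Slc36a1, a lysosomal amino acid transporter, from 4.57 ± 2.79 to 12.4 ± 2.44 FPKM. Foxm1 had 2 of 8 annotated transcripts listed and Myo5a 4 of 14, and the remaining genes of largest rise had few listed too. Exosc10, a subunit of the RNA exosome, was listed at 0 in all 3 WT libraries and at 14.1, 14.2 and 9.01 FPKM in Pth1rΔNLS, with 1 of 8 transcripts listed. Psd3 (1.25 ± 1.02 to 7.01 ± 0.485 FPKM, 2 of 15 listed), Rev3l (0, 0.0118 and 0 FPKM in WT, 2.20 ± 0.885 FPKM in Pth1rΔNLS, 1 of 7), Dpm1 (1.56 ± 0.696 to 7.23 ± 3.22 FPKM, 2 of 10) and Fam110b (0.109, 0 and 0.138 FPKM in WT, 2.02 ± 1.15 FPKM in Pth1rΔNLS, 1 of 9) also rose. Calls were lost for Slc36a1 without any library but WT 2 (adjusted p 0.0824 to 0.115), Fam110b without any but Pth1rΔNLS 3 (0.0692 to 0.0842), Dpm1 without WT 1, WT 3 or Pth1rΔNLS 1 or 2 (0.0592 to 0.0758) and Psd3 without Pth1rΔNLS 3 (0.0522) or with a pseudocount of 0.1 (0.0510). Without both libraries of extreme mitochondrial share, Foxm1 (0.0681), Slc36a1 (0.157), Fam110b (0.160) and Dpm1 (0.138) did not pass.

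The remaining pathway lists did not pass camera, and their few called members, all outside the naming rule and chosen after their values were seen, went mostly both ways. Of 23 interferon response genes 1 rose, Bst2 (31.8 ± 5.76 to 66.3 ± 4.18 FPKM), and 5 fell, Ifi44 (7.41 ± 1.16 to 1.88 ± 0.0575 FPKM), Gbp2 (11.5 ± 1.07 to 4.17 ± 0.301 FPKM), Ifit3 (-0.58), Ifit3b (-0.53) and Ifit1 (-0.48), also adjusted over the list alone (median -0.21, adjusted p = 0.258). The number lower was 3 without WT 2 and 2 without any other library or without both libraries of extreme mitochondrial share. Of 15 inflammatory genes 2 rose, Nfkbia (0.39) and Ccl2 (0.32), and 2 fell, Saa3 (-0.71) and Csf1 (-0.35), against 3 and 2 adjusted over the list alone (median 0.05, mean -0.07, camera upward, adjusted p = 0.561), and of 12 antigen presentation genes 1 fell, H2-Ab1 (-0.99), also adjusted over the list alone (median -0.11, adjusted p = 0.758). Of 33 oxidative phosphorylation genes 1 rose, Ndufa5 (0.60), and 1 fell, Cox6c (-0.59), against 0 and 0 adjusted over the list alone (median -0.01, mean 0.0045, camera upward, adjusted p = 0.758). Of 24 glycolysis and hypoxia genes 1 rose, Gpi1 (0.89), and 2 fell, Adm (-0.46) and Vegfa (-0.32), also adjusted over the list alone (median 0.09, adjusted p = 0.147). Of 21 unfolded protein response genes 2 rose, Atf3 (0.78) and Sdf2l1 (0.50), and 2 fell, Chac1 (-0.62) and Asns (-0.35), also adjusted over the list alone (median -0.08, adjusted p = 0.796). Of 12 heat shock genes 1 rose, Hspa1b (0.42), and 1 fell, Hspb1 (-0.52), against 3 and 1 adjusted over the list alone (median 0.10, adjusted p = 0.408), and of 14 clock genes 1 rose, Tef (0.69), and 1 fell, Bhlhe40 (-0.33), also adjusted over the list alone (median 0.01, adjusted p = 0.883). Leaving out 1 library moved the medians to between -0.23 and -0.07 for interferon, -0.02 and 0.11 for inflammatory and -0.16 and 0.0004 for antigen presentation genes. They ran from -0.03 to 0.03 for oxidative phosphorylation, 0.07 to 0.17 for glycolysis, -0.09 to -0.02 for the unfolded protein response, -0.0041 to 0.17 for heat shock and -0.03 to 0.07 for clock genes. The small counts of called members moved with single libraries too. Inflammatory genes higher numbered 1 without WT 1 or Pth1rΔNLS 3 and 0 without WT 3, Pth1rΔNLS 1 or Pth1rΔNLS 2, and those lower 1 without WT 2, WT 3 or Pth1rΔNLS 1 and 0 without the others. The antigen presentation count was 0 without WT 1 or WT 3. For oxidative phosphorylation 0 were higher without WT 2, WT 3, Pth1rΔNLS 2 or Pth1rΔNLS 3, and 0 lower without any library but Pth1rΔNLS 1. Glycolysis genes higher numbered 2 without WT 1, and those lower 1 without WT 1, Pth1rΔNLS 1 or Pth1rΔNLS 3 and 0 without WT 3 or Pth1rΔNLS 2. In the unfolded protein response 1 was higher without any 1 library, and 1 lower without WT 1, Pth1rΔNLS 1 or Pth1rΔNLS 2 and 0 without WT 3 or Pth1rΔNLS 3. Heat shock genes higher numbered 0 without WT 1, Pth1rΔNLS 2 or Pth1rΔNLS 3, and those lower 0 without WT 1, WT 3, Pth1rΔNLS 1 or Pth1rΔNLS 3. Clock genes higher numbered 0 without Pth1rΔNLS 1 or Pth1rΔNLS 3, and those lower 0 without any library but WT 2 or Pth1rΔNLS 2.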

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

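The tests on rescaled nuclear genes, on genes with an exact 0 in no library or with 1 listed transcript, and without the 2 libraries of extreme mitochondrial share were chosen only after the result was seen. Other pseudocounts, filters, scalings, limma options, rescaled nuclear genes and genes without an exact 0 left the count of changed genes within 1.5 times 1886. Quantile normalization gave 915 higher and 1007 lower, with 1 sign change among the 1886 (Fth1, encoding ferritin heavy chain, named after its values were seen), and rescaled nuclear genes 870 and 1024, with 0. Leaving out 1 library gave 1051 to 1712 changed genes, 348 to 695 higher and 703 to 1017 lower, with fewer samples, and Pth1r at -1.35 to -1.03 on the log2 scale. Leaving out WT 1 and Pth1rΔNLS 1 gave 620 genes (191 higher, 429 lower), of which 583 were among the 1886, and Pth1r at -0.97 (adjusted p = 0.108), with fewer samples. Genes with 1 listed transcript gave 1131 (410 higher, 721 lower) and transcripts tested singly 896 (311 higher, 585 lower), each from a different number of tests, and a log2 fold change of at least 1 gave 320 (35 higher, 285 lower). The replicate block gave 792 genes (232 higher, 560 lower). Same-numbered libraries deviated from their group means with correlations of -0.189, -0.0664 and 0.0657, and 0 samples correlated best with their own number. With 3 pairs this check cannot exclude a shared preparation, and the labels do not say what the numbers mean, so the block stays a possible design. The block also left Thra, Runx2, Cd22, Sox9, Col2a1, Col10a1, Emcn, Cdh5, Pf4, Idi1, Itgb3, Casp12, Fam110b, Slc36a1 and the chondrocyte list (adjusted p = 0.0516) not past the threshold. An estimated correlation passed 8 lists and fry's mixed test 26. These numbers answer different questions, since the mixed test asks for members changed in either direction and camera for a shift against other genes. Without both libraries of extreme mitochondrial share, Col2a1, Col10a1, Sox9, Cd36, Fabp4 and Lpl lost their calls too. Several values that never passed changed direction, and the cause was not tested. Cd4 was at -0.0118 without Pth1rΔNLS 1, up to 0.195 without another library, and at -0.0964 without both libraries. Over left-out libraries the adjusted p ran from 0.481 for oxidative phosphorylation, from 0.593 for the unfolded protein response and from 0.782 to 0.976 for clock genes. Lists turned at adjusted p of 0.980 (oxidative phosphorylation without WT 3), 0.950 (the same without Pth1rΔNLS 2), 0.995 (unfolded protein response without Pth1rΔNLS 1), 0.942 (clock without Pth1rΔNLS 3), 0.961 (clock without a filter), 0.965 and 0.916 (interferon and unfolded protein response at a mean of at least 5 FPKM) and 0.942 for both antigen presentation and unfolded protein response without both libraries. Medians of lists that did not pass turned too, to -0.02 for inflammatory genes without Pth1rΔNLS 2, -0.0041 for heat shock without WT 3, -0.13 for thyroid hormone receptors, transport and cofactors over genes with 1 listed transcript and 0.01 for interferon at a mean of at least 5 FPKM. The antigen presentation median was 0.0004 without WT 1 and 0.04 without both libraries. The clock median (-0.11 over genes with 1 listed transcript to 0.12 at a mean of at least 5 FPKM) and that of oxidative phosphorylation (-0.03 without Pth1rΔNLS 2 to 0.06 without both libraries) turned in several alternatives. A mean of at least 5 FPKM also took the thyroid hormone response median to 0.02 and the inflammatory median to 0.21. Over genes with 1 listed transcript, which are fewer, the median was -0.14 for marrow stromal genes and osteoclast support factors, -0.69 for senescence and 0.09 for parathyroid hormone targets, and with no filter 0.26 for adipocyte genes. Of 89 named genes past the threshold, 63 kept their call in all alternatives, and 1 named gene, Cd4, turned in any. Tests on counted reads were not run because depth is unknown, and FPKM do not show how precisely low genes were measured.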

Other observations

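The extra gene lists, the lists of restricted markers, the tests of mixture in both lists, the rescaling test on mesenchymal genes, the change of scale and the test of cell cycle against macrophage genes were chosen only after the result was seen. Because the extra lists were chosen that way, their list p-values are no independent test. Lysosomal genes were higher in Pth1rΔNLS libraries, 15 of 37 with 0 lower (median log2 fold change 0.31, camera adjusted p = 0.0327 with an estimated correlation). The same libraries had 14 of 20 macrophage genes higher (median 0.43). For the lysosomal and the oxidant list, a change in cell shares and a change within cells were therefore not told apart. Ctsd, encoding cathepsin D, rose from 799 ± 83.4 to 1334 ± 55 FPKM and Lipa, lysosomal acid lipase, from 240 ± 13.8 to 388 ± 16 FPKM (limma adjusted p = 0.00415 and 0.00168). Oxidant response genes rose too, 12 of 18 with 0 lower (median 0.44, 0.0327), among them Hmox1, encoding heme oxygenase 1 (539 ± 44.5 to 931 ± 34.4 FPKM) and Srxn1, a sulfiredoxin (35.9 ± 5.80 to 62.5 ± 3.62 FPKM). The number of lysosomal genes higher was 8 without WT 1, WT 3 or Pth1rΔNLS 2, 7 without Pth1rΔNLS 3 and 3 without both libraries of extreme mitochondrial share. For oxidant genes it was 8 without Pth1rΔNLS 2 and 5 without both. Fc receptors and C-type lectins of myeloid cells (11 of 20 higher, median 0.52; adjusted p = 0.0827 with an estimated correlation), CC chemokines (5 of 12, 0.183) and proton pump subunits (4 of 16, 0.0735) rose at the preset correlation alone, beside 14 of 20 macrophage genes. Of the lectin list 7 were higher without WT 1, WT 3, Pth1rΔNLS 1 or Pth1rΔNLS 2 and 5 without both libraries of extreme mitochondrial share, when 2 chemokine genes were.

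Genes regulated by cell contact and actin fell, 18 of 24 with 0 higher (median -0.85; adjusted p = 0.0327 with an estimated correlation), again with 14 of 20 macrophage genes higher. Thbs1, encoding thrombospondin 1, fell from 2413 ± 107 to 1103 ± 16.5 FPKM, Ccn1 from 372 ± 9.17 to 173 ± 7.40 FPKM, Vcl, encoding vinculin, from 146 ± 1.69 to 75.7 ± 3.21 FPKM and Fhl2 from 133 ± 5.57 to 45.4 ± 2.32 FPKM. Acta2 and Ccn2, in this list, also stand in lists fixed in advance. The lists of 25 ribosome biogenesis and 13 mitochondrially encoded genes passed as higher at the preset correlation alone (adjusted p = 0.0242 and 0.00300; 0.428 and 0.469 with an estimated correlation), with 1 and 0 members higher and 0 lower. The ribosome biogenesis median of 0.10 was 0.03 without WT 2 (1 higher and 1 lower), 0.06 without Pth1rΔNLS 2, 0.15 without Pth1rΔNLS 1 and 0.17 without both libraries of extreme mitochondrial share. The mitochondrially encoded median of 0.52 was 0.27 without WT 1, 0.30 without Pth1rΔNLS 1, 0.04 without both and 0.82 without WT 2, when 1 member was higher. It was 0.14 under quantile normalization. Those of 78 ribosomal protein genes (0.299 and 0.712) and 38 histone genes (0.224 and 0.469) passed with neither. All these genes were chosen after their values were seen.

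The 10 splits of the 6 libraries are too few for a share under 0.05: 1 of the 10, the real one, gave 1886 genes, and the highest of the others gave 4. The other splits put both genotypes in each group, so any genotype difference widens their spread and lowers their counts. The 4 is therefore not the count to be had without a difference, and no conclusion is drawn from it.

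Mesenchymal genes fell while macrophage genes rose, which may reflect a change in the shares of these cells. If mixture were the whole cause, mesenchymal genes would fall by a shared factor. But 7 of 24 mesenchymal-restricted genes differed from the list's mean change on log2(FPKM), and the same 7 on log2(FPKM + 1), narrowly over an arbitrary bound of 25%. Relative to that mean, 4 were lower (Col1a1, Col5a2, Col3a1 and Col12a1) and 3 higher (Ddr2, Pcolce and Col6a3). Col6a3 lay furthest from it (1.14 on log2(FPKM)), at 29.3 ± 3.03 FPKM in WT and 34.3 ± 4.25 FPKM in Pth1rΔNLS. The test takes all 24 as restricted to mesenchymal cells, which was not checked here, so it argues only weakly. Of the 20 macrophage genes 1, Laptm5, differed from their mean change on either scale. A mixture shift as the whole cause would leave no gene apart, and 1 gene is under the bound of 25%. The test therefore cannot tell, which leaves that explanation open for them. The mesenchymal median was -0.74 after rescaling nuclear genes and -0.78 before. Rescaling moves all nuclear genes of a library by 1 factor, and the median of all genes went from -0.0107 to 0.0215. The mitochondrial shares fixed that factor, so this was no test of the mesenchymal genes themselves. It does show that scaling by mitochondrial transcripts was too small to be the whole cause. Mixture as part of the cause, a shift among kinds of mesenchymal cell and an effect of the genotype within cells stay open, and no cell numbers were used here.

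Cell cycle genes rose, which could come from more macrophages carrying them at a constant level, or from more division in either cell type. Relative to the mean of the macrophage list on log2(FPKM), where a shift in cell shares is a shared factor, 8 of 30 cell cycle genes rose (median 0.20) and 2, Rrm2 (-0.29) and Pcna (-0.24), fell, against 7 and 2 on log2(FPKM + 1) (median 0.13), which understates low genes. The 8 lie narrowly over the bound of 25% and the 7 under it, so a constant level in macrophages as the whole cause is argued against on the first scale alone and weakly. The cell cycle median was 0.58 after rescaling nuclear genes and 0.55 before. The mitochondrial shares fixed that outcome too, so it was no test of these genes. It shows only that scaling by mitochondrial transcripts slightly lowered nuclear genes in Pth1rΔNLS, which is opposite to the rise. Which cells divided, and an effect of the genotype on division, stay open.

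Some transcripts were listed at 0 in all libraries of 1 genotype and above 0 in all of the other: 110 transcripts of 105 genes, 56 at 0 in WT and 54 at 0 in Pth1rΔNLS. Reads assigned to transcripts at random could give this, and the highest of the other splits gave 67. The bound of 1.5 times that number, 100.5, was passed by less than the counting spread of 10.5, a margin asked for only after the number was seen. Of the 110, 36 belonged to genes past the threshold, which can produce the pattern too, so chance assignment and a change of transcript cannot be told apart here. Exosc10 is such a gene, and its rise may be a matter of which of its 8 annotated transcripts received reads.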
